A study of Mus musculus with 15 samples.

How the data were processed

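The series holds bulk RNA sequencing of whole mouse ileum from 15 libraries, 5 in each of 3 genotypes. Control mice carried floxed Tak1 alleles (WT), the second group had lost TAK1 in intestinal epithelial cells (TAK1 IEC-KO, HO), and the third combined that loss with 2 copies of the Ripk1 D138N allele, which makes a RIPK1 protein without kinase activity (DHO). TAK1 is the product of Map3k7. Deletion was induced with 3 daily intraperitoneal doses of 80 mg/kg tamoxifen, and tissue was taken 3 days post induction. Total RNA was extracted with TRIzol and made into libraries with a VAHTS Universal V6 kit. The labels give no batch, sex, litter or pairing, and the replicate numbers follow only the order of deposition, so libraries were not paired and no batch could be tested.

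The deposited table gives 1 value per gene and library for 25329 gene symbols. Per the submitters' processing notes, fastp, HISAT2, HTSeq and the mm10 genome were used, without versions, settings or the annotation. The unit of the deposited values is FPKM (reads scaled to gene length and library depth), which was read from the values themselves because the file names none. Within a gene each value was a whole number of reads times a step set by gene length and library depth. Whole reads, within a tolerance of 0.02 of a read, were recovered this way for 99.99% of genes with a value above 0. The recovered depths ran from 38724782 reads (WT 2) to 40590052 (HO 3). In accession order the depths were 39018779, 38724782, 39342855, 39859863, 39563446 in WT, 39940776, 39307699, 40590052, 39575421, 39522640 in HO and 39366060, 40381590, 40229557, 40087689, 39056223 in DHO. The reads carry no molecular identifiers, so read counts describe counting error only.

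Genes with at least 1 FPKM in at least 5 libraries were kept, which left 11332. A gene low elsewhere could pass through the 5 libraries of 1 group, so counts of list members tested favour genes high in that group. Changes are differences of group means of log2(FPKM + 1), and their standard errors (SE) and p-values come from limma-trend with robust variance moderation (limma 3.58.1, R 4.3.3), in 1 fit of group means over all 15 libraries. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. FPKM values are given as mean ± SD over the 5 libraries of a group. Because 1 FPKM was added before the log, changes of genes near or below 1 FPKM are drawn toward 0. Coordinates are on GRCm38.p6, the assembly behind mm10, from RefSeq genes matched by symbol; 11313 of the genes tested had a match.

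The comparisons, tests, 38 gene lists and the rule for naming genes were fixed before the data were examined. The rule named 9 genes of the RIPK1 pathway in every comparison. It added, in each comparison, up to 6 genes with the largest rise and 6 with the largest fall among called genes with separate groups and a mean of at least 1 FPKM. It also took up to 4 members of each list with the smallest p, up to 2 more that were not called, and the sex-linked genes. Genes named outside the rule are said to be so, and some results of genes within it are not reported here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 105 tests of lists with at least 3 members tested. Camera with an estimated correlation and fry were run beside it, and members were counted over all genes and adjusted over the list alone.

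Opposite calls in HO against WT and DHO against HO were counted, because both comparisons share the HO libraries. They were set beside the overlap of independent lists and beside 20 fits in which separate HO libraries served each comparison, and the correlation of the 2 changes was set beside 50 simulations with no effect. The share of the HO change that remained in DHO was measured over 100 combinations, with genes and signs chosen on 3 HO and 3 WT libraries and changes measured on the other 2 of each. The workflow was tested on simulated data built from the recovered reads: it recovered 82.7% of genes given a 2-fold change and 95% of those given a 4-fold change, with 3.8% false calls, and found 25.2% remaining where 25% was put in. Only 200 genes were changed there, as many up as down. Genes were drawn independently around WT means, without a shift common to many genes or libraries that stood apart. The real data differ in these points, so these rates need not hold for them.

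Alternatives fixed in advance were other filters, thresholds and pseudocounts, quantile normalization, a smooth muscle covariate, fits of only the 2 groups compared, and leaving out each library in turn. Alternatives chosen after seeing the data were limma-voom on the recovered reads, with library totals or with median-of-ratios factors, FPKM divided by median-of-ratios factors, array weights, and leaving out either of 2 sets of 3 libraries described with the data. Other alternatives set in advance that needed a deposited count table were not applicable, and the planned count test of recovered reads was replaced by limma-voom. Scaling mattered in these data: the median change of all genes tested was -0.249 in HO against WT and 0.246 in DHO against HO, and it was centred near 0 by the median-of-ratios and quantile scalings.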

Results

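Whole ileum was sequenced 3 days after tamoxifen from 5 WT, 5 HO and 5 DHO mice, to address the role of RIPK1 kinase activity in the ileitis of mice that lack TAK1 in the intestinal epithelium. Depth was even, between 38724782 and 40590052 reads per library, and 11332 genes were tested. The first principal component, with 54% of the variance, placed the HO libraries between 26.2 and 67.3 and the WT and DHO libraries between -28.6 and -17.7. The second component held 18% of the variance and was highest in HO 1 (50.1), DHO 4 (32.8) and DHO 3 (30.6).

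Those 3 libraries held transcripts of the proximal small intestine. Gata4, a transcription factor of the duodenum and jejunum, stood at 27.3 FPKM in HO 1, 19.04 in DHO 3 and 18.04 in DHO 4, and at 0.529 or below in each of the other 12 libraries. HO 1 also held 1 read of Fabp6, the ileal bile acid binding protein, against 139933 to 237712 reads in WT libraries. DHO 3 and DHO 4 held Fabp6 at 95.7% and 105% of the WT mean, while Hoxb9, a positional gene of the distal gut, stood at 3.02% and 2.71%. The B cell gene Ms4a1 was at 8.81 FPKM in HO 2, 15.5 in HO 4 and 7.04 in DHO 1, and at 0.286 or below in the other libraries. Gata4, Hoxb9 and Ms4a1, and Lct, Fabp1 and Slc25a48 shown with them, were named after their values were seen. Xist was at 0.0126 FPKM or below in all 15 libraries, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were expressed in every group. Pairs of libraries within a group were also compared by a chi-square of their reads, where a lower value means a closer pair. DHO 3 and DHO 4 were the closest, at 13.37 per gene, against 54.34 or more for other DHO pairs. WT 1 and WT 2 (16.79) and WT 3 and WT 4 (22.99) were close too. The labels give no litter, so whether such pairs are independent could not be tested.

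**Figure D1:**
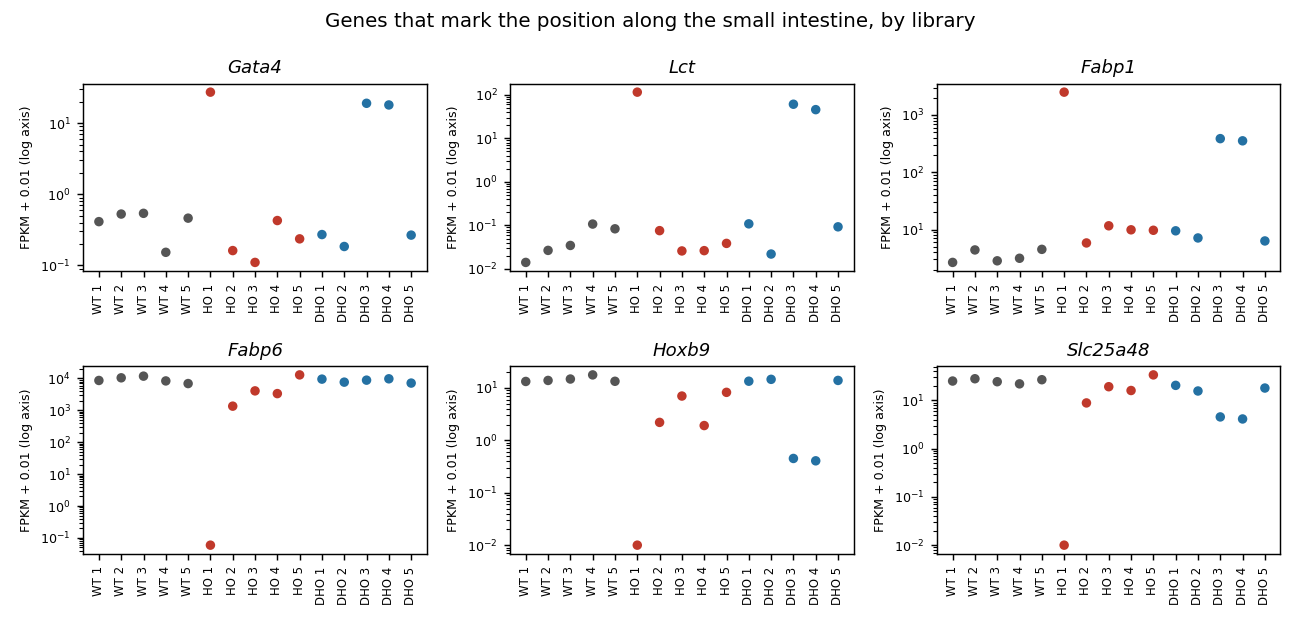
Expression of 6 genes that differ along the small intestine, in FPKM with 0.01 added on a log axis, with 1 point per library (WT grey, HO red, DHO blue). HO 1, DHO 3 and DHO 4 stand apart for Gata4, Lct and Fabp1, and HO 1 alone lacks Fabp6.

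The first comparison, HO against WT, asked what deleting TAK1 in the intestinal epithelium changed in the ileum. Most interferon response genes and most cytokine and chemokine genes tested rose in HO. Cell cycle genes, the stem cell gene Olfm4 and most Paneth cell markers tested fell. The secreted protease inhibitor gene Serpina3n rose from 2.15 ± 1.72 to 55.4 ± 35.9 FPKM, a log2 change of 4.01 (SE 0.45, adjusted p = 9.25e-06). The monocyte-attracting chemokine gene Ccl2 rose by 3.66 (SE 0.40, adjusted p = 7.71e-06) and the interferon-induced GTPase gene Gbp2 by 3.60 (SE 0.36, adjusted p = 3.48e-06). Olfm4 fell by 5.24 on the log2 scale (SE 0.50, adjusted p = 2.51e-06), from 120 ± 64.4 to 2.60 ± 2.72 FPKM, and was lower in all 5 HO libraries than in any WT library.

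In all, 6273 genes passed the test, 1406 higher and 4867 lower in HO, and 1298 of them changed by a doubling or more. The 5 HO libraries lay wholly on one side of the 5 WT libraries for 36% of genes, where chance gives 0.79%. The median-of-ratios factors of the libraries were separate as well, at 0.758 to 0.983 in HO and 1.016 to 1.22 in WT. A shift common to many genes can thus raise that share, which was not measured after scaling. The median change of all genes tested was -0.249, so a gene that did not move relative to the others would appear to fall by about that amount. The lower share of the calls, 77.6%, became 53.4% with median-of-ratios scaling and 55.7% with quantile normalization. Among the other genes named by size, the metallothionein gene Mt2 (3.89), Rasd1 (3.76) and Apoa4 (3.71) rose, and Gsdmc4 (-4.26), Cyp2c55 (-4.14), the desaturase gene Scd2 (-3.79), Fgfbp1 (-3.52) and Acta1 (-3.29) fell. Apoa4, a lipoprotein gene most expressed in the proximal small intestine, was at 16400 FPKM in HO 1 and between 853.5 and 2629 in the other HO libraries. Without HO 1 the change was 3.03 for Apoa4 and 2.98 for Rasd1, and without HO 5 it was -4.4 for Scd2.

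Map3k7 (chromosome 4, 31963492 to 32023470), the gene targeted, was at 10.4 ± 0.80 FPKM in WT, 8.66 ± 1.04 in HO and 9.23 ± 0.71 in DHO. Its log2 change in HO was -0.24 (SE 0.09, adjusted p = 0.0419), about the median change of all genes. That call was lost with quantile normalization, where the change was 0.02, and with median-of-ratios scaling, where it was 0. It was also lost without any 1 of WT 2 (adjusted p = 0.0936), WT 3 (0.0742), WT 4 (0.0969), HO 1 (0.0991), HO 3 (0.0622), DHO 1 (0.0527) or DHO 3 (0.0511). Whole ileum holds cells in which the gene was not deleted, and removing floxed exons can leave the rest of a transcript.

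Genes of the necroptosis and death receptor pathway rose in HO. Mlkl, the executor of necroptosis, rose from 6.93 ± 1.19 to 17.8 ± 3.20 FPKM (log2 change 1.24, SE 0.14, adjusted p = 7.26e-06), and the kinase gene Ripk3 from 21.6 ± 0.98 to 43.5 ± 8.61 FPKM (0.95, SE 0.17, adjusted p = 0.000377). Zbp1, a nucleic acid sensor upstream of RIPK3, rose by 2.04 (SE 0.24), Casp8 by 0.55 (SE 0.11), the TNF receptor gene Tnfrsf1a by 1.10 (SE 0.14) and Tnf by 1.00 (SE 0.15). Ripk1 itself (chromosome 13, 34002225 to 34035170) rose by 0.33 (SE 0.08, adjusted p = 0.00348), and the adaptor gene Fadd fell by 0.81 on the log2 scale (SE 0.16). Tradd did not pass (0.13, adjusted p = 0.294), but it did with quantile normalization (0.24) and both median-of-ratios scalings (0.39 and 0.45). Of 26 cell death genes tested, 11 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.68e-05; adjusted p = 0.0868 with an estimated correlation).

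**Figure D2:**
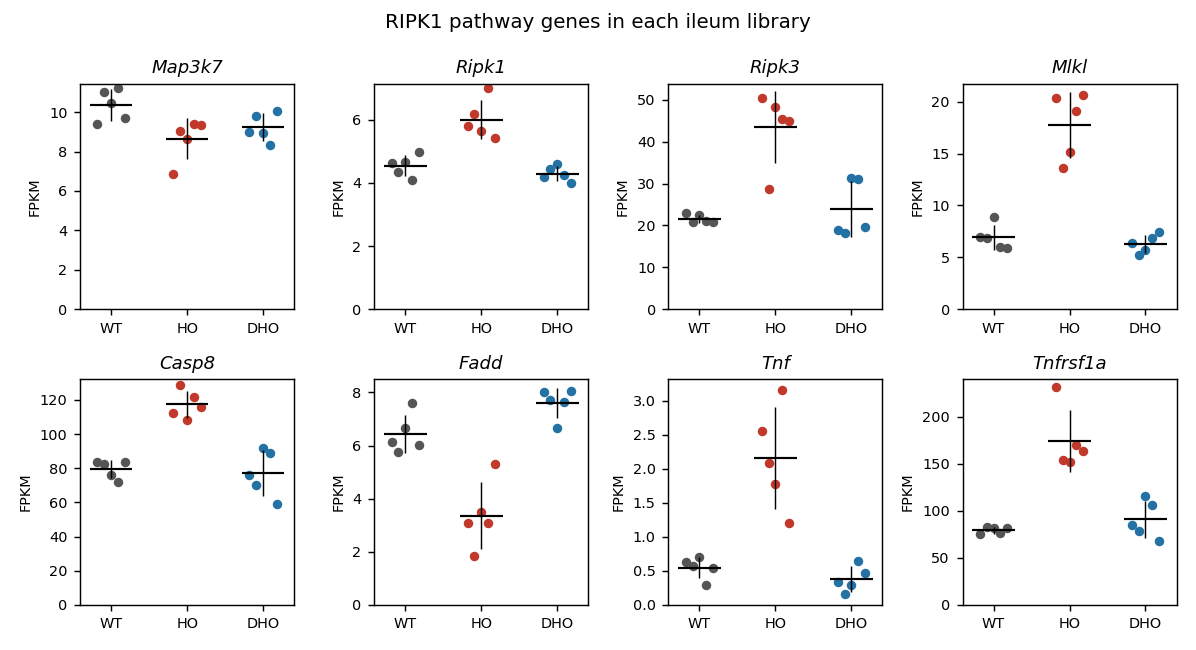
FPKM of Map3k7 and 7 genes of the RIPK1 pathway, with 1 point per library, the group mean as a horizontal line and its SD as a vertical line (n = 5 per genotype). Ripk1, Ripk3, Mlkl, Casp8, Tnf and Tnfrsf1a lie higher in every HO library than in any WT library. Fadd lies lower in every HO library than in any WT library, and Map3k7 overlaps between WT and HO.

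Interferon and inflammatory genes rose as groups in HO. All 28 type I interferon response genes tested rose, over all genes and adjusted over the list alone, among them Usp18 (3.29, SE 0.34) and Oas2 (2.89, SE 0.31). The camera adjusted p was 9.97e-26 (adjusted p = 0.102 with an estimated correlation). Of 22 interferon gamma response genes 18 rose, 19 adjusted over the list alone, including Iigp1 (3.32, SE 0.33) and Gbp4 (2.58, SE 0.22), with a camera adjusted p of 8.24e-18 (adjusted p = 0.0868 with an estimated correlation). Irf1 was at 0.50 (adjusted p = 0.0594). Of 28 cytokines and chemokines listed, 12 passed the filter and 8 rose, 9 adjusted over the list alone, among them Cxcl10 (3.28, SE 0.40) and Ccl7 (2.65, SE 0.31). Their camera adjusted p was 6.59e-07 (adjusted p = 0.15 with an estimated correlation). Tnf passed the filter through HO libraries only, so this count favours genes high in HO. Antigen presentation genes divided, with 11 higher, such as Tap2 (1.36) and Tapbp (0.98), and 4 lower of 19 (12 and 4 adjusted over the list alone; camera adjusted p = 6.77e-05, and 0.326 as the adjusted p with an estimated correlation). None of the 4 was called lower under quantile or either median-of-ratios scaling. Of 16 NF-kB feedback genes, 5 rose and none fell, as also adjusted over the list alone, with Tnfaip3 at 0.77 and Icam1 at 1.35 (camera adjusted p = 0.000538; adjusted p = 0.286 with an estimated correlation). Nfkbie was at 0.45 (adjusted p = 0.0525).

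Transcripts of proliferation genes, and of some stem, Paneth and goblet cell markers, were lower in HO. All 24 proliferation genes tested were lower, also adjusted over the list alone, and 23 of them were under each of quantile and both median-of-ratios scalings. Mki67 fell from 10.7 ± 1.63 to 1.51 ± 0.42 FPKM (-2.22, SE 0.17), Ccna2 by 2.68 (SE 0.20) and Ccnb2 by 2.55 (SE 0.17), with a camera adjusted p of 1.59e-10 for the list (adjusted p = 0.226 with an estimated correlation). Of 12 stem cell markers 7 fell, 8 adjusted over the list alone, including Ascl2 (-1.14, SE 0.19) and Cdca7 (-1.91, SE 0.19), while Rnf43 was at -0.38 (adjusted p = 0.0541). That list did not pass camera (adjusted p = 0.0718) and passed fry (adjusted p = 0.00148). Paneth cell markers fell for 11 of 16, also adjusted over the list alone, with the lysozyme gene Lyz1 at -2.42 (SE 0.49) and Ang4 at -3.32 (SE 0.68). The camera adjusted p of that list was 0.0441 (adjusted p = 0.76 with an estimated correlation), and it rose above 0.05 without any 1 of WT 2, WT 3, WT 4, HO 1, HO 2, HO 4 or HO 5. In 2 DHO libraries some alpha-defensin genes of this list read as absent. Of 14 goblet cell markers 8 fell, including Spink4 (-1.86, SE 0.31), and 1 rose, the lectin gene Zg16 (0.69, SE 0.11), against 9 and 1 adjusted over the list alone (camera adjusted p = 0.748). With median-of-ratios scaling of FPKM the goblet counts were 6 lower and 4 higher.

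Among other epithelial lists, some regenerative fetal-like and enterocyte genes rose, and most cholesterol synthesis genes fell. Of 15 regenerative fetal-like genes 10 rose and 1 fell, as also adjusted over the list alone. The epidermal growth factor receptor ligand genes Areg (3.43, SE 0.33) and Ereg (2.24, SE 0.25) and the surface antigen gene Ly6a (2.32, SE 0.25) were among the former (camera adjusted p = 7.36e-08; adjusted p = 0.0978 with an estimated correlation). The 1 that fell did not pass under any of the 3 scalings, and Anxa1 was at 0.68 (adjusted p = 0.0764). Of 26 enterocyte genes 14 rose and none fell, also adjusted over the list alone, including the amino acid transporter gene Slc6a19 (1.11, SE 0.14) and the peptidase gene Dpp4 (0.71, SE 0.11), with a camera adjusted p of 9.45e-08 (adjusted p = 0.15 with an estimated correlation). Without HO 1, DHO 3 and DHO 4 the enterocyte counts were 18 higher and 1 lower. Cholesterol synthesis genes fell for 19 of 20, all 20 adjusted over the list alone, with the mevalonate pathway gene Mvd at -2.18 (SE 0.24), and a camera adjusted p of 0.000182 (adjusted p = 0.431 with an estimated correlation). Of 6 bile acid genes 1 rose, none adjusted over the list alone. Fabp6 was at -3.58 (SE 1.78, adjusted p = 0.0998), and at -1.21 (adjusted p = 0.0414) without HO 1, DHO 3 and DHO 4. Of 17 antimicrobial genes 3 rose and 3 fell, 3 and 2 adjusted over the list alone, with the siderophore-binding gene Lcn2 at 2.56 (SE 0.46) and the antibody transporter gene Pigr at -2.39 (SE 0.22; camera adjusted p = 0.0607). Junction genes divided into 3 higher and 5 lower of 12, with 4 and 6 adjusted over the list alone, and Cldn2 (-1.61, SE 0.34) and Ocln (-0.69, SE 0.13) among the latter. The median of that list was -0.37 and camera, which ranks it against the other genes, placed it upward without a call (adjusted p = 0.762).

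Markers of cells outside the epithelium also differed. Of 13 neutrophil markers listed, 3 passed the filter and 2 rose, as also adjusted over the list alone. Ly6g rose from 0.049 ± 0.053 to 10.5 ± 9.59 FPKM and S100a8 from 0.26 ± 0.31 to 3.50 ± 2.19 FPKM. The camera adjusted p of the list was 0.0158 (adjusted p = 0.226 with an estimated correlation). Ly6g reached 1 FPKM in HO libraries only, and S100a8 in HO libraries and DHO 2. The filter thus kept genes high in HO, and the list test is not independent of it. Of 13 macrophage markers 2 rose, Cd68 among them (0.79, SE 0.26), and none adjusted over the list alone. Their camera adjusted p was 0.026 (adjusted p = 0.673 with an estimated correlation), and none was called without the libraries with B cell transcripts. Smooth muscle markers rose for 5 of 13, 1 adjusted over the list alone, with Des at 1.77 (SE 0.49; camera adjusted p = 0.000173, and 0.482 as the adjusted p with an estimated correlation). WT libraries differed widely here: Des was at 18.11 and 17.42 FPKM in WT 1 and WT 2 and at 56.42 to 109 in the other WT libraries. HO libraries held 66.45 to 231.2 FPKM. Enteric neuron and glia markers rose for 6 of 9, 8 adjusted over the list alone, with Tubb3 at 1.63 (SE 0.37; camera adjusted p = 4.68e-05, and 0.283 as the adjusted p with an estimated correlation). Tubb3 too was lowest in WT 1 and WT 2 (0.8253 and 0.9949 FPKM), against 2.967 to 6.377 in the other WT libraries and 5.226 to 16.67 in HO. Endothelial markers rose for 4 of 10, 3 adjusted over the list alone, with Esam at 1.05 (SE 0.18; camera adjusted p = 0.000547, and 0.392 as the adjusted p with an estimated correlation). Without HO 2, HO 4 and DHO 1 no smooth muscle marker was called, and 2 neuronal and 2 endothelial markers were. T and NK cell markers fell for 5 of 14, as also adjusted over the list alone, with Itgae at -0.60 (SE 0.12) and Ccl5 at -0.77 (SE 0.24; camera adjusted p = 0.703), and 1 was called lower with median-of-ratios scaling.

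**Figure D3:**
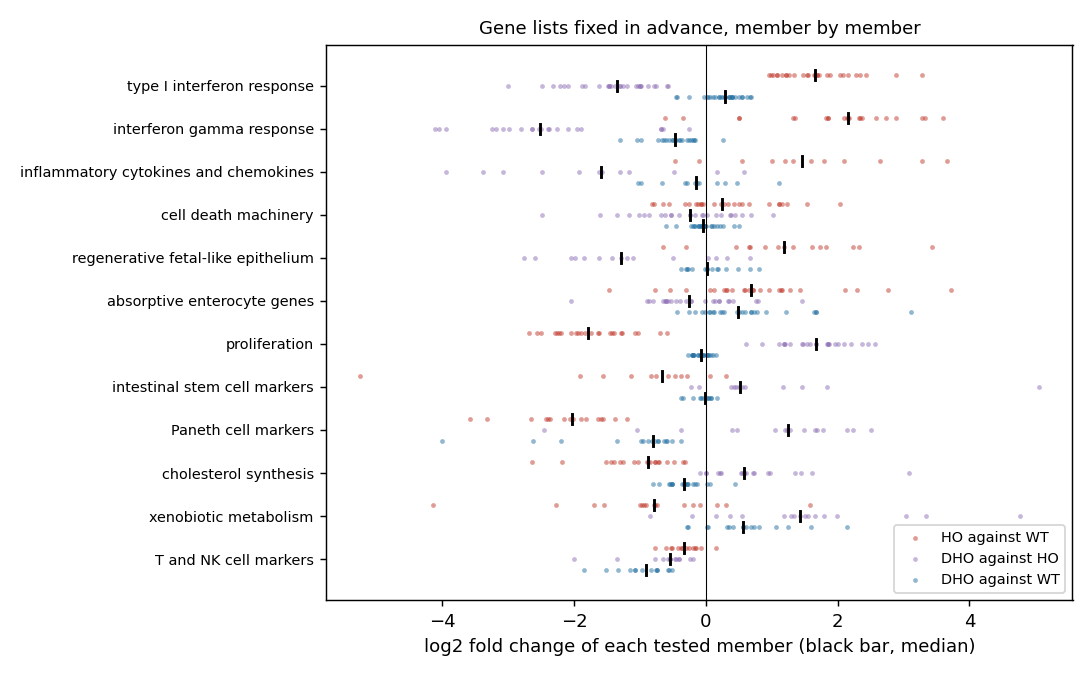
Log2 fold change of each tested member of 12 gene lists in the 3 comparisons (HO against WT red, DHO against HO purple, DHO against WT blue), with the median of each list as a black bar. The type I interferon response has medians of 1.65, -1.34 and 0.29, and proliferation of -1.79, 1.68 and -0.07.

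The second comparison, DHO against HO, asked what RIPK1 without kinase activity changed where TAK1 was deleted. The changes ran opposite to those of HO against WT: most interferon response and chemokine genes tested fell, with Mlkl and Ripk3, and all proliferation genes tested and some stem cell and xenobiotic genes rose. Olfm4 rose by 5.05 (SE 0.50, adjusted p = 2.84e-06) to 97.3 ± 35.9 FPKM, and Gbp2 fell by 4.10 on the log2 scale (SE 0.36, adjusted p = 1.51e-06) to 12.9 ± 3.61 FPKM. The interferon-induced GTPase gene Iigp1 fell by 4.04 on the log2 scale (SE 0.33) and the acute phase gene Saa3 by 4.01 (SE 0.58). Each of these genes separated all 5 DHO from all 5 HO libraries.

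In all, 6359 genes passed, 4846 higher and 1513 lower in DHO, 1338 of them by a doubling or more. Groups were separate for 33.3% of genes, where chance gives 0.79%, a share that a shift common to many genes can raise. The median change of all genes tested was 0.246, and the lower share of the calls, 23.8%, became 44.7% with median-of-ratios scaling and 44% with quantile normalization. Other large rises were in Cyp2c55 (4.76), Gsdmc4 (4.07), Gstm3 (3.35) and the urea cycle gene Cps1 (3.25), and the other largest falls in Cxcl10 (-3.94), Serpina3n (-3.74) and Rasd1 (-3.38). Without HO 1, DHO 3 and DHO 4, Gstm3 was at 2.64 and Cxcl10 at -3.26, and without HO 1 alone Rasd1 was at -2.61 and without HO 5 Saa3 at -4.69.

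Of the RIPK1 pathway, Mlkl fell by 1.35 on the log2 scale (SE 0.14, adjusted p = 3.34e-06) to 6.30 ± 0.89 FPKM, Tnf by 1.17 (SE 0.15), Tnfrsf1a by 0.94 (SE 0.14), Ripk3 by 0.86 (SE 0.17), Casp8 by 0.61 (SE 0.11) and Ripk1 by 0.40 (SE 0.08). Fadd rose by 1.03 (SE 0.16). Tradd was at -0.23 (adjusted p = 0.0581) and passed with quantile normalization (-0.37) and both median-of-ratios scalings (-0.48 and -0.55). Map3k7 was at 0.09 (SE 0.09, adjusted p = 0.446), and at -0.22 (adjusted p = 0.0246) in limma-voom with median-of-ratios factors. Of 26 cell death genes 11 fell, Zbp1 by 2.48 (SE 0.24), and 2 rose, as also adjusted over the list alone (camera adjusted p = 5.20e-05; adjusted p = 0.0868 with an estimated correlation).

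Type I interferon response genes fell for 27 of 28 in DHO against HO, all 28 adjusted over the list alone, with Zbp1, a member of this list too, at -2.48 (SE 0.24; camera adjusted p = 4.75e-21, and 0.148 as the adjusted p with an estimated correlation). Interferon gamma response genes fell for 20 of 22, also adjusted over the list alone, with Gbp4 at -2.98 (SE 0.22) and Nlrc5 at -1.96 (SE 0.18). Their camera adjusted p was 4.75e-21 (adjusted p = 0.0868 with an estimated correlation). Of the 12 cytokines and chemokines that passed the filter 9 fell, also adjusted over the list alone (camera adjusted p = 3.78e-07, and 0.15 as the adjusted p with an estimated correlation). Il18 was at 0.58 (adjusted p = 0.31). Antigen presentation genes fell for 12 of 19, also adjusted over the list alone, with Tap2 at -1.50 (SE 0.14; camera adjusted p = 1.98e-09, and 0.166 as the adjusted p with an estimated correlation). NF-kB feedback genes fell for 6 of 16 and rose for 1, also adjusted over the list alone, with Tnfaip3 at -1.40 (SE 0.14) and Nfkbia at -1.13 (SE 0.17). Their camera adjusted p was 4.55e-05 (adjusted p = 0.226 with an estimated correlation), and none was called higher under the 3 scalings. Regenerative fetal-like genes fell for 9 of 15 and rose for 1, 10 and 1 adjusted over the list alone, with Areg at -2.76 (SE 0.33), Ly6a at -2.59 (SE 0.25) and Plaur at -1.98 (SE 0.19). Their camera adjusted p was 6.20e-07 (adjusted p = 0.102 with an estimated correlation), and again none was called higher under the 3 scalings.

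All 24 proliferation genes rose in DHO against HO, also adjusted over the list alone, with Ccna2 at 2.56 (SE 0.20) and Ccnb2 at 2.37 (SE 0.17; camera adjusted p = 6.53e-10, and 0.245 as the adjusted p with an estimated correlation). Stem cell markers rose for 8 of 12, also adjusted over the list alone, with Cdca7 at 1.84 (SE 0.19) and Ascl2 at 1.17 (SE 0.19; camera adjusted p = 0.1, fry adjusted p = 0.00194). Xenobiotic metabolism genes rose for 12 of 17, also adjusted over the list alone, including the carboxylesterase gene Ces2a (1.34, SE 0.20) and the efflux pump gene Abcc2 (1.98, SE 0.30; camera adjusted p = 0.0451, and 0.392 as the adjusted p with an estimated correlation). That camera call was lost without any 1 of HO 2, HO 4, HO 5, DHO 3 or DHO 4. Cholesterol synthesis genes rose for 14 of 20, also adjusted over the list alone, with Mvd at 1.62 (SE 0.24; camera adjusted p = 0.0482, and 0.76 as the adjusted p with an estimated correlation), and 1 was called lower in limma-voom with median-of-ratios factors. That camera call was lost without any 1 of WT 4, WT 5, HO 1, HO 2, HO 4, DHO 1 or DHO 2. Paneth cell markers rose for 7 of 16, 6 adjusted over the list alone, with Ang4 at 2.50 (SE 0.68) and Itln1 at 1.69 (SE 0.45), and without HO 1, DHO 3 and DHO 4 the counts were 4 higher and 3 lower (camera adjusted p = 0.633). Mmp7 was at 1.05 (adjusted p = 0.0672). Goblet cell markers rose for 7 of 14 and fell for 1, also adjusted over the list alone (camera adjusted p = 0.736). Enterocyte genes fell for 4 of 26 and rose for 1, 3 and 0 adjusted over the list alone, with Slc6a19 at -0.87 (SE 0.14) and Apoa4 at -2.05 (SE 0.85, adjusted p = 0.0511). Their camera adjusted p was 0.00109 (adjusted p = 0.326 with an estimated correlation), and 9 fell with median-of-ratios scaling of FPKM. Of 6 bile acid genes, 1 rose and 1 fell, also adjusted over the list alone, with the hormone gene Fgf15 at 2.75 (SE 0.75, adjusted p = 0.00598), which was at 1.15 (adjusted p = 0.08) without HO 1, DHO 3 and DHO 4, and Fabp6 at 3.49 (adjusted p = 0.107).

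Some T and NK cell, macrophage and plasma cell markers were lower in DHO than in HO, and neither of the 2 B cell markers tested was called. Of 14 T and NK cell markers 7 fell, also adjusted over the list alone, with the cytotoxic granule genes Gzmb at -2 (SE 0.31) and Gzma at -1.35 (SE 0.28; camera adjusted p = 1.80e-06, and 0.226 as the adjusted p with an estimated correlation). Of 13 macrophage markers 7 fell, also adjusted over the list alone, with C1qa at -1.26 (SE 0.33; camera adjusted p = 0.000212, and 0.392 as the adjusted p with an estimated correlation). Without HO 2, HO 4 and DHO 1, 1 of them was called and C1qa was not (adjusted p = 0.0601), nor was it without HO 1, DHO 3 and DHO 4 (adjusted p = 0.054). Of 4 plasma cell markers all fell, also adjusted over the list alone, with Jchain at -1.05 (SE 0.31; camera adjusted p = 0.0059, and 0.276 as the adjusted p with an estimated correlation). None was called without HO 1, DHO 3 and DHO 4. Ly6g fell by 2.89 on the log2 scale (SE 0.51). Of 17 antimicrobial genes 6 fell and 1 rose, also adjusted over the list alone, with the lectin gene Reg3b at -1.28 (SE 0.20; camera adjusted p = 0.000705, and 0.102 as the adjusted p with an estimated correlation), though Reg3b was not called with quantile normalization (-0.22, adjusted p = 0.317).

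Genes called in both comparisons almost always moved in opposite directions. Of 5480 such genes, 5477 were opposite, 1152 of them higher in HO and lower again in DHO, such as Mlkl and Cxcl10, and 4325 lower in HO and higher in DHO, such as Olfm4 and Ccna2. That was 87.3% of the genes called in HO against WT. Independent lists of the same sizes would share 188 and 2081. When separate HO libraries served each comparison, 2830 to 4126 opposite calls were made, with at most 74 in the same direction. Across genes the 2 changes had r = -0.921, against -0.446 in 50 simulations with no effect, where the shared HO libraries alone set it, and genes are not independent replicates. The part of the HO change that remained in DHO was 2.3% (range -9.2 to 12.1 over 100 combinations of libraries, which share mice), and it was 2% with median-of-ratios scaling. It was less well fixed for rising genes alone, at 3.6% (range -75.5 to 17.7), than for falling genes alone, at 3.3% (range -14.1 to 19.2).

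**Figure D4:**
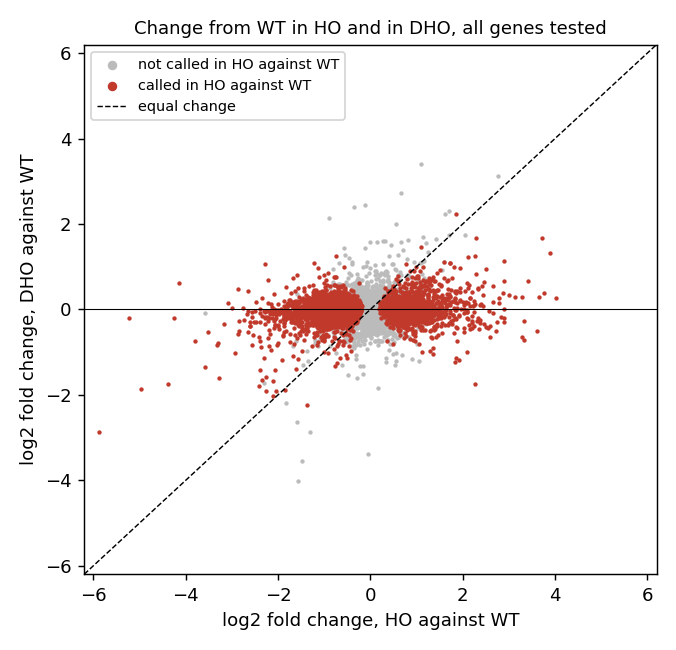
Log2 fold change from WT in HO (horizontal axis) and in DHO (vertical axis) of the 11332 genes tested, with 1 point per gene, red where called in HO against WT. The red points spread along the horizontal line at 0, and the dashed line marks an equal change in both.

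The third comparison, DHO against WT, asked what differed from the control when TAK1 was deleted and RIPK1 lacked kinase activity. No group carried the Ripk1 allele with TAK1 intact, so a difference cannot be assigned to the loss of TAK1 or to that allele. T and NK cell markers such as Cd3e and Itgae, and the single genes Pigr and Ccl28, were lower in DHO, and 9 genes, Pdzk1 among them, were higher. The T cell receptor subunit gene Cd3e fell from 4.32 ± 0.48 to 1.71 ± 0.16 FPKM (-0.97, SE 0.14, adjusted p = 0.00736), and Itgae, an integrin subunit of intraepithelial lymphocytes, from 4.00 ± 0.31 to 1.80 ± 0.20 FPKM (-0.84, SE 0.12, adjusted p = 0.00929). Pigr, which carries IgA across the epithelium, fell from 750.1 ± 77.4 to 280.4 ± 20.3 FPKM (-1.41, SE 0.22, adjusted p = 0.0118), and Ccl28, a chemokine for antibody-secreting cells, from 16.1 ± 2.21 to 4.77 ± 1.42 FPKM (-1.60, SE 0.22, adjusted p = 0.00523). Pdzk1, a scaffold protein of brush border transporters, rose from 64.7 ± 6.35 to 128.5 ± 19.1 FPKM (0.97, SE 0.12, adjusted p = 0.0025).

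In all, 27 genes passed, 9 higher and 18 lower in DHO, and 719 did at an unadjusted p under 0.05. Groups were separate for 4.4% of genes, where chance gives 0.79%. Of the 18 lower genes, 13 were also called lower in HO against WT, 1 higher and 4 not called, and of the 9 higher genes 2 were called higher, 2 lower and 5 not called. The 2 comparisons share the WT libraries, and 4867 of the 11332 genes tested were called lower in HO. Among the falls, the others named by size were Ceacam10 (-1.78, SE 0.16, adjusted p = 4.99e-05), Cd177 (-1.68, SE 0.15, adjusted p = 4.99e-05), Plet1 (-2.25), Gzmb (-1.84) and U90926 (-1.60). Ceacam10 and Cd177 lie close together on chromosome 7 (24777167 to 24784656 and 24743983 to 24760334). Among the rises they were the pyrimidine salvage gene Cda (2.24, SE 0.40), Serpinb9b (1.21), the glycerol channel gene Aqp7 (0.99), Rnd2 (0.87) and Fmo5 (0.77). Cda was at 32.1 ± 23.8 FPKM in HO and 40.6 ± 23.9 in DHO, against 6.79 ± 1.22 in WT, and its change in DHO was 1.65 without HO 1, DHO 3 and DHO 4. Of the genes named here, Cda, Serpinb9b, Rnd2, Fmo5, Plet1, Gzmb, U90926 and Pigr, and Ccng1 below, each lost the call without at least 1 single library, WT 2 among them for each. The count was sensitive to the fit, at 11 without WT 2, 76 without HO 1 and 186 when only the 2 groups were fitted. So was the balance of directions, at 91 higher and 95 lower in that fit, 189 and 157 with array weights, and 27 and 23 without HO 1, DHO 3 and DHO 4. The HO libraries enter this comparison only through the shared estimate of the spread, so the count of 27 depends on the spread within HO as well.

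Of the RIPK1 pathway, none of the 9 genes passed in DHO against WT: Ripk3 was at 0.10 (SE 0.17), Mlkl at -0.11 (SE 0.14), Casp8 at -0.06 (SE 0.11), Tnf at -0.17 (SE 0.15), Tnfrsf1a at 0.17 (SE 0.14), Fadd at 0.21 (SE 0.16), Tradd at -0.11 (SE 0.10), Ripk1 at -0.07 (SE 0.08) and Map3k7 at -0.15 (SE 0.09). Their adjusted p was 0.962 for Map3k7 and 0.9996 for each of the others. Olfm4 was at -0.19 (SE 0.50), Mki67 at -0.27 (SE 0.17) and Areg at 0.67 (SE 0.33, adjusted p = 0.857). No cell death, proliferation, stem cell or regenerative gene was called over all genes, and adjusted over the list alone 2 cell death genes were higher and 1 lower, and none of the other 3 lists.

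T and NK cell markers made the largest group among the calls. Of 14 tested 8 fell, and all 14 fell adjusted over the list alone, with Nkg7 at -1.15 (SE 0.16), Cd3g at -1.07 (SE 0.17) and Gzmb at -1.84 (SE 0.31). The camera adjusted p was 1.08e-32 and stayed under 0.05 with an estimated correlation (adjusted p = 0.0333), as no other call among the 105 tests of the lists fixed in advance did. Zap70 (-0.56, adjusted p = 0.162) and Lck (-0.73, adjusted p = 0.259) were not called over all genes. Over all genes 3 members were called with median-of-ratios scaling of FPKM and 2 in limma-voom with those factors, and 8 without HO 1, DHO 3 and DHO 4. Gzmb was not called with either median-of-ratios scaling (adjusted p = 0.0619 and 0.0727).

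**Figure D5:**
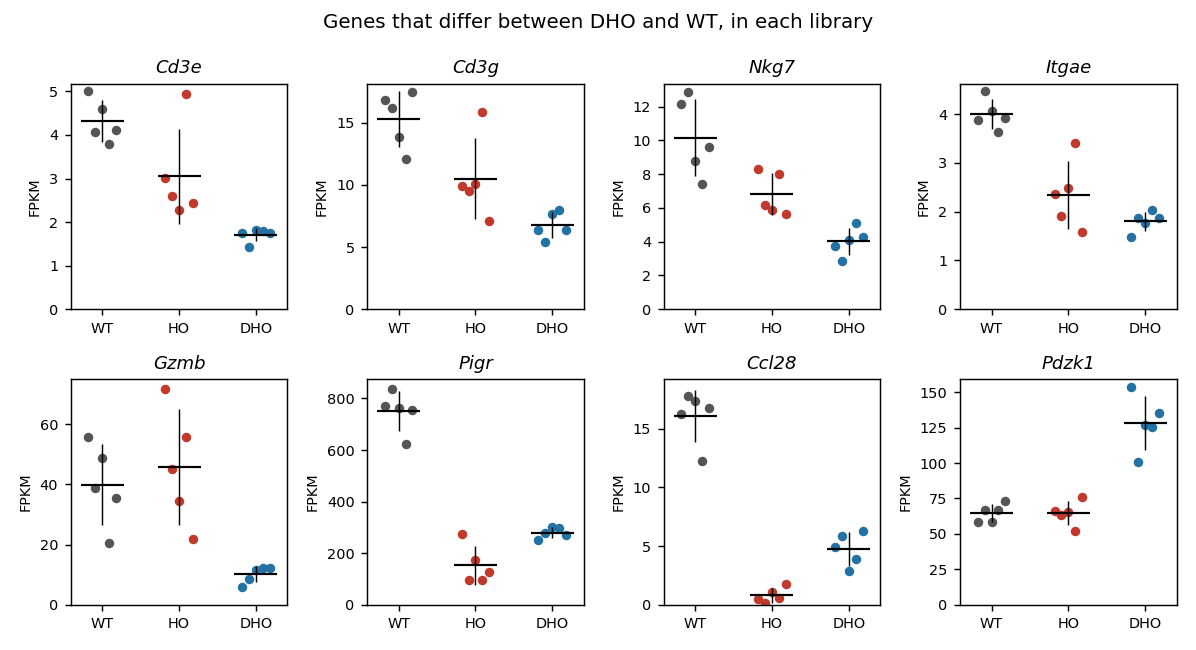
FPKM of 8 genes called in DHO against WT, with 1 point per library, the group mean as a horizontal line and its SD as a vertical line (n = 5 per genotype). The 5 DHO libraries lie wholly below the 5 WT libraries for Cd3e, Cd3g, Nkg7, Itgae, Gzmb, Pigr and Ccl28, and wholly above them for Pdzk1.

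Other lists had at most 1 gene called over all genes between DHO and WT. No antigen presentation gene was called over all genes, and 8 of 19 were lower adjusted over the list alone, where Cd74 stood at -0.93 (SE 0.27) and H2-DMa at -0.76 (SE 0.16; camera adjusted p = 1.03e-09, and 0.161 as the adjusted p with an estimated correlation). Interferon gamma response genes had 0 calls, and 2 of 22 lower adjusted over the list alone (camera adjusted p = 6.77e-09, and 0.169 as the adjusted p with an estimated correlation), with Cd274 at -1.05 (adjusted p = 0.0968) and Nlrc5 at -0.64 (adjusted p = 0.216). Type I interferon response genes had 0 calls in both counts and a median of 0.29, with Rtp4 at 0.68 (adjusted p = 0.267; camera adjusted p = 2.99e-05, and 0.452 as the adjusted p with an estimated correlation). Of 17 p53 target genes the cyclin gene Ccng1 rose (0.73, SE 0.13, adjusted p = 0.0321), and 5 were higher adjusted over the list alone (camera adjusted p = 6.97e-05, and 0.154 as the adjusted p with an estimated correlation). Phlda3 was at 0.71 (adjusted p = 0.216). Of 4 plasma cell markers none was called, and 3 were lower adjusted over the list alone, with Jchain at -1.53 (SE 0.31, adjusted p = 0.056) and Mzb1 at -1.32 (SE 0.32; camera adjusted p = 1.03e-06, and 0.102 as the adjusted p with an estimated correlation). Of 17 antimicrobial genes Pigr was called, and 6 were lower and 1 higher adjusted over the list alone, with Retnlb at -1.89 (adjusted p = 0.0736; camera adjusted p = 3.68e-06, and 0.0846 as the adjusted p with an estimated correlation). No enterocyte, xenobiotic or cholesterol gene was called, and adjusted over the list alone 1 enterocyte gene, Alpi (0.78, SE 0.16), was higher, 2 xenobiotic genes were higher and 3 cholesterol genes lower. The camera adjusted p was 9.11e-08 for enterocyte genes, 1.04e-06 for xenobiotic genes and 5.57e-08 for cholesterol genes (adjusted p = 0.15, 0.0978 and 0.252 with an estimated correlation). Without HO 1, DHO 3 and DHO 4 the median change was 0.27 for enterocyte genes and 0.28 for xenobiotic genes, in place of 0.49 and 0.57, with 2 and 0 genes called higher. Among other cell type markers, 4 lists had 0 calls in both counts and passed camera only at the preset correlation. Paneth cell markers (median -0.80), macrophage markers (-0.39) and endothelial markers (-0.30) were placed downward, and smooth muscle markers (0.68) upward. In the Paneth list the alpha-defensin gene Defa21 was at -4.01 (adjusted p = 0.774), with 0 reads in DHO 1 and 1 in DHO 5 and 8317 to 21007 in the other DHO libraries. The camera adjusted p of these 4 lists was 7.79e-06, 5.27e-05, 0.000538 and 0.00129 (adjusted p = 0.354, 0.354, 0.392 and 0.595 with an estimated correlation), and without WT 2 it was 0.0901 for smooth muscle markers. None of the 4 passed fry (adjusted p = 0.26, 0.249, 0.269 and 0.478).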

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

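The tests of a mixed sample and of genotype for the proximal libraries, and the 3 tests of the alpha-defensins, were chosen only after the result was seen. Comparisons, lists and thresholds were set before the data were examined.

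In each comparison the true grouping called more genes than any other of the 100 splits tried. That made 1 of 100, the lowest share these splits could give. It argues against a chance division of the libraries but cannot exclude it. The splits also cannot address a batch, litter or gut position tied to genotype. The real values were 6273 in HO against WT, 6359 in DHO against HO and 27 in DHO against WT, and the highest of the other splits called 2318, 2338 and 0.

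More genes fell than rose in HO against WT, 77.6% of those called. Leaving out HO 1, DHO 3 and DHO 4 gave 72.8%, and a smooth muscle covariate gave 81.8%. This argues against those 3 libraries and against muscle wall as the whole cause. A smaller difference in gut position is not addressed. HO 2, HO 3, HO 4 and HO 5 held Gata4 at 0.417 FPKM or below, but also less Hoxb9, at 1.908 to 8.244 FPKM against 13.31 to 17.76 in WT. Whether position or genotype gave that lower Hoxb9 was not tested. Abundant genes taking a larger share of the reads stay open: the 100 genes with the most reads held 30.2 to 35.8% of the reads in HO and 25.5 to 30.5% in WT, and scaling to the other reads moved the median change from -0.249 to -0.171, between the bounds set in advance, with 70.3% of the calls lower. Median-of-ratios scaling gave 53.4%, which met the bound written before and would have counted for abundant genes as the cause. The scaling centres the median by construction, so this test was set aside as void and decides nothing. A fall of many transcripts with the genotype may also be part of the excess of falling genes. The 2 causes cannot be told apart without a measure of total RNA per cell.

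HO 1, DHO 3 and DHO 4 held Gata4, Lct and Fabp1 far above the other libraries. Ileal RNA mixed with RNA of a proximal sample is argued against, since Hoxb9 was at most 3.02% of the WT mean in DHO 3 and DHO 4, where Fabp6 was at 95.7% and 105%. Genotype as the only cause is argued against as well, since 7 of the 7 other HO and DHO libraries held Gata4 at or below the highest WT library. Gata4 was among the genes that set the 3 libraries apart, so this value restates that division and is no separate test. A piece from another position of the small intestine, or a mislabelled sample, could also give these values, and neither was tested.

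Some alpha-defensin genes read as absent in some libraries: Defa21 had at most 10 reads in 2 libraries, DHO 1 and DHO 5, and Defa27 in 6 libraries; both genes were named after their values were seen. Fewer Paneth cells are argued against as the whole cause in DHO 1 and DHO 5. The median of 5 other Paneth markers was 27.2% of the WT mean in DHO 1 and 94.7% in DHO 5, with Defa21 at 0% and 0.0054%. In DHO 1 fewer Paneth cells could still be part of it. In the libraries without Defa27 the median of the 5 other markers was 54.6% in DHO 3 and 66.3% in DHO 4, but 8.47 to 17.4% in HO 1, HO 2, HO 4 and HO 5. Fewer Paneth cells could be part of it in these HO libraries. As the whole cause they are argued against, since these libraries held 889 to 11001 reads of Defa21 and 0 of Defa27. WT libraries held 781 to 2780 reads of Defa27. Copies of the gene cluster that differ between mice may also be involved and stay open: 0 libraries lacked both Defa21 and Defa27, but libraries drawn at random would share none with a probability of 0.343. Reads shared between these paralogs were not tested.

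A library stood far from the other 4 of its group in 24 of 357 pairs of gene and group (6.7%), where chance gives about 1 in 20; the figure after each gene is the gap to the nearest library as a share of the range, both on log2(FPKM + 1), against a critical value of 0.71. HO 1 stood apart for Map3k7 (0.721, lowest at 6.88 FPKM against 8.63), Tnfrsf1a (0.733, highest at 231 against 170), Cubn (0.751, lowest), Fabp6 (0.76, lowest) and Alpi (0.819, highest). HO 5 stood apart for Tradd (0.781, highest), Scd2 (0.782, highest at 72.5 against 10.7), Lcn2 (0.732, lowest), Saa3 (0.886, lowest at 12.9 against 128) and Jchain (0.778, lowest). Of the other HO libraries, HO 2 was lowest for Ripk3 (0.792, 28.7 against 44.8) and HO 3 for Rtp4 (0.815). DHO 2 was lowest for Usp18 (0.785), Slc6a19 (0.944), Nr1d1 (0.782) and Cd3e (0.801), and highest for S100a8 (0.838). DHO 5 was highest for Mki67 (0.825) and Ly6g (0.867) and lowest for H2-DMa (0.719). Among WT libraries, WT 3 was highest for Usp18 (0.806), WT 4 lowest for Tap2 (0.742) and Ccl28 (0.763), and WT 2 highest for Ceacam10 (0.74).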

How the results depend on the processing

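The limma-voom tests, median-of-ratios scalings, array weights and the fits without the proximal or the B cell libraries were chosen only after the result was seen. With at least 5 FPKM required, 4151, 4168 and 15 genes were called (HO against WT, DHO against HO, DHO against WT), where fewer genes were tested. With a doubling or halving required they were 1298, 1338 and 16, with 1007 opposite calls, by construction of the threshold, as were the 7 in DHO against WT at an adjusted p under 0.01. DHO against WT also gave 186 when only the 2 groups compared were fitted. The HO libraries enter that comparison only through the shared estimate of the spread, so that estimate, not the size of the changes, set this difference. The count was 346 with array weights, 11 in limma-voom with median-of-ratios factors and 15 with FPKM divided by median-of-ratios factors. It was 50 and 47 without the proximal and the B cell libraries, and the cause of these other counts was not tested. The first 2 counts and the opposite calls stayed within 1.5 times under the other alternatives, at 6484, 6193 and 5436 without the proximal libraries and 4965, 4683 and 3981 without the B cell libraries. Leaving out 1 library gave 5608 to 6681, 5821 to 6780 and 11 to 76 calls, and 4898 to 5964 opposite calls. For DHO against WT the count moved by over 1.5 times without WT 1 (12), WT 2 (11), WT 3 (14), WT 5 (16), HO 1 (76), HO 4 (45), HO 5 (54), DHO 1 (15) or DHO 4 (17). Map3k7 in HO against WT turned from -0.24 to 0.02 with quantile normalization, 0.06 in limma-voom with median-of-ratios factors and 0 with FPKM divided by those factors, and in DHO against HO from 0.09 to -0.22; these scalings move the median of all genes, and a further cause was not tested. In DHO against HO, fry placed p53 targets (adjusted p = 0.0157) and fatty acid oxidation genes (adjusted p = 0.0103) upward where camera placed them downward without a call; the cause was not tested. With an estimated correlation 21, 23 and 15 list calls were lost. With fry 5, 4 and 9 were lost, and 2, 1 and 0 were gained in the direction camera gave. Lost in HO against WT were macrophage (fry adjusted p = 0.612) and smooth muscle markers (0.167) among others. Type I interferon response genes were among those lost in DHO against WT (fry adjusted p = 0.322). Of the genes named, limma-voom with library totals changed 0 of 73 calls in HO against WT, 0 of 53 in DHO against HO and 4 of 48 in DHO against WT, and with median-of-ratios factors 9, 4 and 12. The planned count test of recovered reads, and the alternatives that need a deposited count table, were not run. The share of the HO change remaining in DHO was 2.3%, and 2% with median-of-ratios scaling. Depth was within 38724782 to 40590052 reads, and genes under 1 FPKM were not tested.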

Other observations

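The median-of-ratios scalings were chosen only after the result was seen, and the tests of the 2 hypotheses below before it.

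Immediate early genes were higher in HO than in WT for 6 of 10 tested and lower for 1, as also adjusted over the list alone (camera adjusted p = 0.000496; adjusted p = 0.275 with an estimated correlation), and in DHO against HO 5 were lower and 1 higher. Circadian clock genes moved both ways, with 1 higher and 4 lower of 10 in HO against WT, Per1 at 0.79 and the output gene Dbp at -1.12, and 4 higher and 2 lower in DHO against HO, Dbp at 1.88 and the repressor gene Nr1d1 at 1.54. Neither clock comparison passed camera (adjusted p = 0.972 and 0.978). Tuft cell markers were higher for 3 of 7 and enteroendocrine markers higher for 2 and lower for 1 of 11 in HO against WT, 2 and 0 adjusted over the list alone (camera adjusted p = 0.0139 and 0.0179; adjusted p = 0.207 and 0.226 with an estimated correlation).

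Xenobiotic metabolism genes fell for 9 of 17 and rose for 1 in HO against WT, with Cyp2c55 at -4.14 (camera adjusted p = 0.623, fry adjusted p = 0.00565), and 3 fell under either median-of-ratios scaling. The p53 targets divided into 4 higher and 4 lower of 17 in HO against WT, with a median of -0.15 that camera placed upward (adjusted p = 0.222). Of 13 mitochondrially encoded genes 1 was lower in HO against WT, none adjusted over the list alone, with a median of -0.26 that camera placed upward (adjusted p = 0.978).

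A hypothesis was that sequence carried along with the Ripk1 allele gives some of the DHO against WT calls. Within 10 Mb of Ripk1, 1 called gene was found, Serpinb9b, where 0.16 were expected (Fisher exact p = 0.144). The bound written before, none or 1 called gene, was met and would have counted against passenger sequence around Ripk1. After the value was seen that bound was judged wrong, because 1 gene is already more than the number expected, so the hypothesis stays open. Of the genes tested within 10 Mb of Map3k7, 53.2% were called in HO against WT, against 55.4% of all (Fisher exact p = 0.77), which decides nothing, since both groups carried the floxed allele. The rule set before the values were seen would have counted this against the idea, and the test was set aside as void after they were seen.

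A second hypothesis was that HO mice may share a stress or fasting signature with raised glucocorticoid targets. Of 7 such genes tested, 3 were higher in HO than in WT (camera p = 0.000211, and 0.0845 with an estimated correlation), with Errfi1 at 2.21 and Per1 at 0.79, while Fkbp5 was at 0.90 (adjusted p = 0.0541). In DHO against HO 5 were lower (camera p = 1.52e-06, and 0.0311 with an estimated correlation), and in DHO against WT the list was lower with 0 genes called (camera p = 4.83e-06, and 0.0387 with an estimated correlation). The rule set before, a camera p under 0.05 in HO against WT, was met and would have counted for the hypothesis. But the libraries differed by gene: HO 5 lay above each WT library for Errfi1 and Per1 and below each for Fkbp5 and Sgk1. HO 1 lay below each for Klf9 and Cdkn1c. The hypothesis was therefore left open after these values were seen. Some of these genes also respond to inflammation or growth factors, which was not tested.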
